A study of Homo sapiens with 12 samples.

How the data were processed

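Total RNA of MCF-7 xenograft tumours was turned into biotinylated antisense cRNA and hybridized to Affymetrix GeneChips, per the labels' protocols. The deposited table holds log2 values of 54675 probe sets for 12 arrays, and its unit was read from the values, which lie between 2.25 and 16.3. The submitters' processing notes name limma, with no version and no stated role. The background correction, summarization and normalization methods are not given in the sources used here. All arrays share the lowest value of 2.25, held by 15069 to 16890 probe sets per array. The array medians ran from 2.66 to 2.81, a range of 0.152.

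The plan set before the data were examined asked for quantile normalization where medians differ by more than 0.1, so the 12 arrays were quantile normalized over all probe sets and values at the floor were set back to a common floor. Gene names came from the platform annotation, where 41091 probe sets have 1 gene symbol, 1801 several and 11721 none, and 62 are controls. Of these, 41037 were matched to a current symbol through the gene identifier and 0 symbols changed. Probe sets with several symbols or none were left out of the gene tests, and some genes are therefore not analysed here. Each of 19775 genes was represented by the probe set with the highest mean over all 12 arrays (9252 genes have 1 probe set and 10523 more than 1). No filter on low values was used in the reported fit, and 1897 genes lay at the floor on all arrays.

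Groups were taken from the labels: 3 arrays each of control, estradiol, isoflavone mix and soy flour. Group means were fitted for all 12 arrays together with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3. Each of 6 comparisons was tested two-sided with Benjamini-Hochberg adjustment over all genes at 0.05, and a moderated F test asked for any difference among the 4 groups. Values are group means ± SD on the log2 scale with n = 3, and differences are differences of log2 means. The prior degrees of freedom were 0.49, so each gene's test rests mainly on its own spread.

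A total of 26 gene lists written before the data were examined was tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists within each comparison. No list in any of the 6 comparisons passed with an estimated correlation, where the smallest adjusted p were 0.182, 0.3, 0.0523, 0.62, 0.0866 and 0.068. Fry called 7, 3, 18, 0, 5 and 12 lists in the same order (mix, soy flour and estradiol against control, soy flour against mix, mix and soy flour against estradiol). It does not compare a list with other genes. For each list the members past the gene test were counted adjusted over all genes and adjusted over the list alone.

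Named genes were chosen by a rule written before the data were examined. In the 4 main comparisons these are the 8 largest increases and 8 largest decreases among genes past the test whose higher group mean reached the median of all gene values, 4.66 (or the 5 with the smallest p in each direction where none passed). Up to 4 members with the smallest p in each described list and 9 fixed genes were added. In the comparisons against estradiol the 4 largest each way and the fixed genes were named. Genes with all 3 arrays of a group at the floor were not ranked, since their change has no measured size.

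Genes past the test in estradiol against control were followed as sets in the other comparisons. Correlations of changes against the shared control arrays were set beside 100 simulations of unchanged groups. The fit was tested on simulated data with 200 changed genes over 5 runs. In isoflavone mix against control 29.0% of changes of 1 log2 and 80.6% of changes of 2 log2 were recovered, and 5.03% of calls were false. In soy flour against isoflavone mix the recovery was 31.0% and 79.8%, with 5.94% false calls. False calls were 6.13% in soy flour against control and 8.72% in estradiol against control, above the nominal rate. Across 30 simulated comparisons with no change, 2 genes were called in all.

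Alternatives were the values as deposited, arrays centred on their medians, removal of the 40% of genes with the lowest mean, the mean of all probe sets of a gene, every probe set tested, eBayes with trend and robust, array weights, a 1.5-fold minimum, an adjusted p of 0.1, fits of the 6 arrays compared, a replicate block, and leaving out each array. Covariates for the actin 3' minus 5' difference and for the hybridization spikes were chosen after seeing the data, and so was the choice of estradiol genes from 6 arrays alone.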

Results

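Gene expression was measured in MCF-7 tumours grown in ovariectomized athymic nude mice. MCF-7 is a human breast cancer cell line that carries the estrogen receptor. The labels place the 12 arrays in 4 groups of 3. Control mice had a sham pellet and no genistein, estradiol mice a pellet with 2 mg estradiol and no genistein. The other mice ate a purified isoflavone mix or soy flour, each with 750 ppm genistein aglycone, an isoflavone that binds estrogen receptors. The labels do not say whether these mice had a pellet, so diet and control mice may differ in more than the diet. The age at assignment was 28 days in all groups. Tumours were taken 12 weeks after the cells were inoculated. The arrays carry 54675 probe sets for human transcripts, and 27.6% to 30.9% of them sat at the common lowest value of 2.25 log2 on each array. With 3 arrays per group, the number of arrays limits the precision of every value below. The p-values measure only the spread between arrays, since the labels do not say that each array comes from a separate mouse.

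Estradiol and control arrays formed groups of their own, while the arrays of the 2 diets lay close together. The first principal component held 39.5% of the variance and ran from the estradiol arrays to the control arrays, with the arrays of both diets between them. The second held 21.1% and set the diet arrays apart from the control and the estradiol arrays. The actin 3' minus 5' difference, a measure of RNA integrity, had means of 2.94 with the mix and 2.01 with soy flour. It was 1.09 in control and 1.45 in estradiol, and soy flour array 3 was an exception among the diet arrays, at 1.28. Diet and RNA integrity were not separated on this component. Correlations between arrays of the same group were 0.987 to 0.997, and those between groups 0.965 to 0.992. The highest correlation between groups joined mix array 2 and soy flour array 1, and it exceeded the lowest within either diet. Of 19775 genes, 2859 differed among the 4 groups by limma's F test with Benjamini-Hochberg adjustment. That count was 1420 without estradiol array 1, 1606 without estradiol array 2 and 1732 without control array 1.

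**Figure D1:**
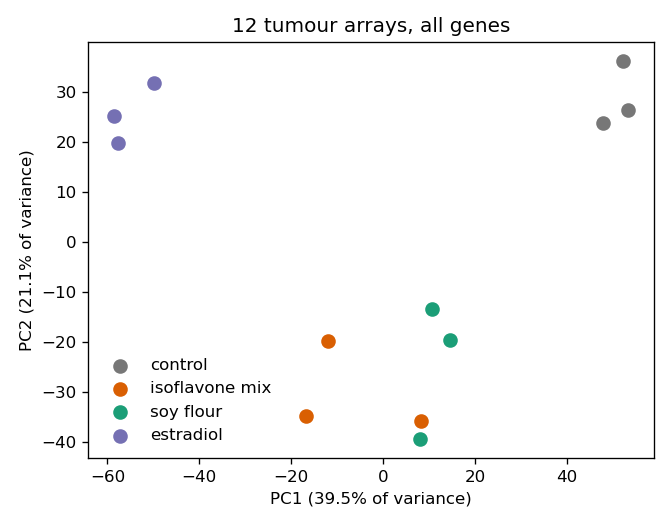
Principal components 1 and 2 of the 12 arrays over all genes, in component units; each point is an array and its colour the group. Component 1 holds 39.5% and component 2 holds 21.1% of the variance.

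The first question was what the isoflavone mix changed against control. TFF1, a small secreted protein whose gene is a standard target of the estrogen receptor, rose from 9.72 ± 1.11 to 14.90 ± 0.34 log2 (SD, n = 3; difference 5.18, adjusted p = 0.00255). MGP, the matrix Gla protein, rose by 3.62 (adjusted p = 0.0148), and the secreted proteins MUCL1, MSMB and FAM3B rose by 4.03, 4.24 and 3.62. SPIN4, PLCL1 and SH3BGRL rose by 6.16, 3.85 and 6.72 log2. SH3BGRL varied most in the control arrays, at 4.62 ± 2.80 with 1 of 3 at the floor, and its adjusted p was 0.0281. LTF, the iron-binding protein lactoferrin, fell from 10.36 ± 0.04 to 4.14 ± 0.13 (difference -6.22, adjusted p = 0.00158). COL1A1, a chain of type I collagen, fell by 5.31, the matrix protein gene THBS4 fell by 4.77, and the transcription cofactor gene VGLL1 fell by 4.89. ALB, CPB1 and GAS1 fell by 4.55, 4.29 and 4.18. Their means with the mix and that of VGLL1 lay under 2.81, the highest array median, beside the floor of 2.25, so these falls can only be lower bounds. None of the 2 other probe sets of GAS1 had its direction. IL1R1, a receptor for interleukin 1 that estrogen lowers in these cells, fell by 4.31 (adjusted p = 0.00673).

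Among the 9 genes fixed for every comparison, ATM, a kinase of the DNA damage response, rose by 1.72 with the mix (adjusted p = 0.013). CDH1, which encodes E-cadherin, fell by 1.10 (adjusted p = 0.0224). The estrogen receptor gene ESR1 was 0.79 higher with adjusted p = 0.0524, and 3 of its 8 other probe sets had that direction. The progesterone receptor gene PGR was 1.81 higher (adjusted p = 0.163), GREB1 2.48 higher (adjusted p = 0.13) and MYC 0.96 higher (adjusted p = 0.464). The control mean of GREB1 lay beside the floor, so its difference is a lower bound. The cyclin gene CCND1 differed by -0.28 and the proliferation marker MKI67 by -0.09, with adjusted p of 0.699 and 1.

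Some mitotic genes rose with the mix: 10 of 36 measured members rose and 0 fell, 14 when adjusted over the list alone, with a median of 0.59. TOP2A rose by 0.92, AURKA by 1.13, CCNA2 by 1.22 and HMMR by 1.63. Camera, which compares a list with all other genes at a preset correlation, gave adjusted p = 3.05e-08 for the list, and adjusted p = 0.339 with an estimated correlation. Of 19 genes of double-strand break and mismatch repair, 8 rose (8 higher and 1 lower adjusted over the list alone), including BARD1, RAD50, RPA3 and MRE11 (camera adjusted p = 7.44e-05, and adjusted p = 0.182 with an estimated correlation). BRCA1 rose by 1.11 and the pocket protein gene RBL1 by 1.47, while FOXO1 fell by 0.85, in a list of cell-cycle inhibitors and tumour suppressors that showed no shift (camera adjusted p = 0.985). The replication genes RRM2 and GINS1 were the 2 of 36 genes of the G1/S phase and DNA replication that rose (2 adjusted over the list alone). The camera adjusted p of that list was 0.000468, and adjusted p = 0.574 with an estimated correlation, and the list turned to the lower side with the actin covariate (adjusted p = 0.187). Ribosomal protein genes were slightly higher, with 7 of 33 risen, 16 higher and 1 lower adjusted over the list alone, and a median of 0.24 (camera adjusted p = 2.68e-05; adjusted p = 0.227 with an estimated correlation).

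Estrogen-induced genes moved both ways with the mix. Of 41, 7 rose and 3 fell (9 and 4 adjusted over the list alone): RET, a receptor kinase gene, rose by 2.17, while SGK1 fell by 2.46 and ADCY9 by 0.95 (camera adjusted p = 0.0322; adjusted p = 0.485 with an estimated correlation). Of 15 estrogen-repressed genes, 3 fell, adjusted over the list alone also 3: IL1R1, EFNA1 and TGFB3. The median of that list was 0.03, its mean -0.43 and its camera adjusted p 0.291. Of 21 genes of epithelial adhesion and luminal keratins, 11 fell and 1 rose (13 and 1 adjusted over the list alone), among them the claudin genes CLDN4 and CLDN3, by 1.32 and 1.65, and the desmosome gene DSP, by 0.99. That list had a median of -0.95 and a camera adjusted p of 3.75e-06, with adjusted p = 0.228 with an estimated correlation. Of 28 fibroblast and matrix genes, 10 fell (13 adjusted over the list alone), among them POSTN by 3.23, COL5A1 by 2.45 and ACTA2 by 2.17 (camera adjusted p = 8.17e-06; adjusted p = 0.228 with an estimated correlation). The immediate early genes JUNB, JUND, JUN and ZFP36 fell by 0.86 to 1.43, and 6 of the 22 listed genes fell, 7 adjusted over the list alone (camera adjusted p = 0.00141; adjusted p = 0.227 with an estimated correlation). Of 35 interferon-stimulated genes, 5 fell (7 adjusted over the list alone), among them HLA-B by 2.32 and HLA-C by 1.98 (camera adjusted p = 8.17e-06; adjusted p = 0.485 with an estimated correlation). The endoplasmic reticulum chaperone genes HSPA5, PDIA4 and PDIA3 fell by 1.03, 1.52 and 0.90. They belong to the unfolded protein response, where 4 of 21 genes fell, 6 adjusted over the list alone (camera adjusted p = 0.0435; adjusted p = 0.574 with an estimated correlation). The leukocyte markers S100A9 and CORO1A fell by 3.09 (a lower bound, beside the floor with the mix) and 1.78 among 20, 3 adjusted over the list alone (camera adjusted p = 0.00789; adjusted p = 0.182 with an estimated correlation). The glycolysis gene HK2 and the collagen cross-linking gene LOX rose by 1.67 and 1.78 (LOX differed by -0.16 with the mean of its probe sets), and LDHA rose too, among 26 hypoxia-induced genes, 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0279; adjusted p = 0.67 with an estimated correlation). COX7A2, NDUFS1 and COX7B rose by 0.50, 0.61 and 0.77 among 29 genes of oxidative phosphorylation, 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0279; adjusted p = 0.574 with an estimated correlation). Of 14 skeletal muscle markers 0 passed, also adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.0279; adjusted p = 0.578 with an estimated correlation).

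In all, 831 genes were higher and 986 lower with the isoflavone mix, 1817 in total, by limma with Benjamini-Hochberg adjustment. Of all genes, 24.9% had no overlap between the arrays of the groups, where chance gives 10%. On the values as deposited the split was 954 higher and 733 lower, that is 56.6% higher in place of 45.7%. The control probe sets for the 3' and 5' ends of actin differed by 2.94 ± 0.86 log2 on the mix arrays and 1.09 ± 0.26 on the control arrays (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow), while the same measure for GAPDH was 0.37 above control (exact permutation p = 0.3), and 5 genes passed with that difference as a covariate. The total was 749 without mix array 1, 1013 without control array 1 and 1090 without control array 2.

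**Figure D2:**
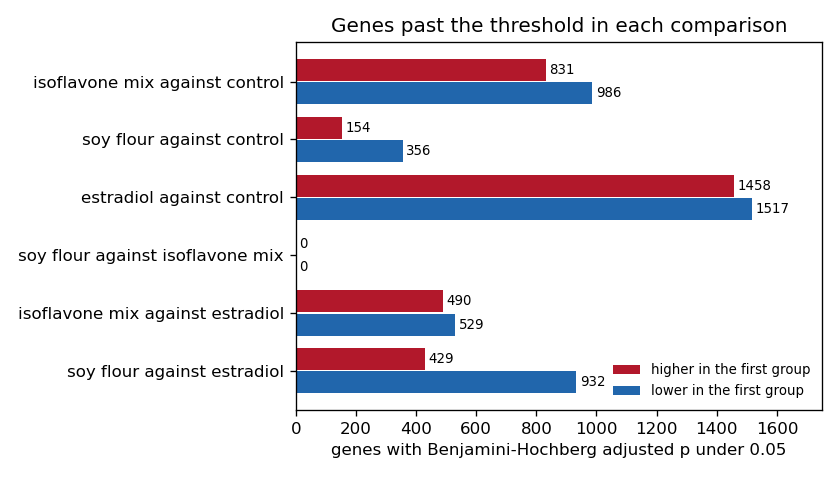
Numbers of genes with an adjusted p under the threshold of 0.05 in each of the 6 comparisons (limma, Benjamini-Hochberg); red bars count genes higher and blue bars genes lower in the group named first. Estradiol against control has 1458 and 1517 genes, and soy flour against isoflavone mix has 0 and 0.

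Soy flour was compared with control to see what the whole food changed at the same genistein content. TFF1 rose to 14.53 ± 0.55 log2 (difference 4.81, adjusted p = 0.00532), and SH3BGRL, MSMB, MUCL1 and MGP rose by 7.09, 4.44, 3.68 and 3.48. LINC01087, a long non-coding RNA, rose by 3.63, TRMT13, a tRNA methyltransferase gene, by 3.41, and the pseudogene SMG1P5 by 3.26. LTF fell by 5.27 (5.09 ± 0.95 against 10.36 ± 0.04, adjusted p = 0.00363), and VGLL1, ALB, CPB1 and THBS4 fell by 4.53, 4.51, 4.33 and 4.16. CRABP2, which carries retinoic acid in the cell, fell by 4.06, the calmodulin-like gene CALML5 by 3.72, and the epithelial transcription factor gene GRHL3 by 3.66. The adjusted p of SH3BGRL was 0.0477. The means of VGLL1, ALB and CPB1 with soy flour again lay beside the floor, so their falls are lower bounds.

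Of the 9 fixed genes, only TFF1 passed the test in soy flour against control. ATM was 1.35 higher (adjusted p = 0.0549) and ESR1 0.62 higher (adjusted p = 0.172). PGR was 1.52 higher, GREB1 2.36, MYC 1.22 and MKI67 0.54, with adjusted p of 0.318, 0.215, 0.44 and 0.441. The difference of GREB1 is again a lower bound, since its control mean lay beside the floor. CDH1 differed by -0.38 (adjusted p = 0.456) and CCND1 by -0.38 (adjusted p = 0.585).

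Of 41 estrogen-induced genes 38 did not pass with soy flour, and the median was 0.30. TFF1 and RET rose and ADCY9 fell (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00241; adjusted p = 0.41 with an estimated correlation). IL1R1 and EFNA1 fell among 15 estrogen-repressed genes, 2 also adjusted over the list alone (camera adjusted p = 0.232). FOXA1, which opens chromatin for the estrogen receptor, rose by 1.93 (adjusted p = 0.027). Of 36 mitotic genes 0 passed the test, 6 when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 9.14e-09; adjusted p = 0.41 with an estimated correlation). Of 36 genes of the G1/S phase and replication 0 passed, 3 adjusted over the list alone (camera adjusted p = 2.77e-05; adjusted p = 0.519 with an estimated correlation). FANCL was the gene that rose among 19 of DNA repair, by 0.80, and 6 were higher and 1 lower adjusted over the list alone (camera adjusted p = 4.98e-05; adjusted p = 0.3 with an estimated correlation). BRCA1 rose by 0.79. Of 21 epithelial adhesion genes, CLDN4, TJP3 and CLDN3 fell, by 1.06, 1.04 and 1.35, and 11 adjusted over the list alone (camera adjusted p = 1.29e-05; adjusted p = 0.41 with an estimated correlation). COL6A1, TWIST1 and COL1A1 fell by 2.23, 1.64 and 2.76 among 28 fibroblast and matrix genes, 10 adjusted over the list alone (camera adjusted p = 0.00718; adjusted p = 0.519 with an estimated correlation). LDHA, the lactate dehydrogenase gene, rose by 1.34 and LOX by 1.90 among 26 hypoxia-induced genes, where 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00718; adjusted p = 0.701 with an estimated correlation). RPS12 and RPL22 rose by 0.60 and 0.52 among 33 ribosomal protein genes, 2 also adjusted over the list alone (camera adjusted p = 0.00283; adjusted p = 0.41 with an estimated correlation). The lipid synthesis gene ACLY rose by 0.54 among 21 genes of cholesterol and fatty acid synthesis, 3 adjusted over the list alone (camera adjusted p = 0.0136; adjusted p = 0.519 with an estimated correlation).

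With soy flour 154 genes were higher and 356 lower than in control (limma, Benjamini-Hochberg), and 22.5% of all genes had no overlap between the arrays of the groups, where chance gives 10%. The actin difference was 2.01 ± 0.65 log2 on the soy flour arrays (exact permutation p = 0.2) and that of GAPDH 0.0102 above control (exact permutation p = 1), and 41 genes passed with the actin difference as a covariate. Over the genes called without it, the median absolute change was 1.14 before and 1.08 after. Their median standard error grew from 0.191 to 0.234. The count was 109 without soy flour array 1, 326 without array 2, 294 without array 3, 227 without estradiol array 1 and 260 without estradiol array 2. In simulated data with the spread of these genes and 200 changed genes, 29.4% of changes of 1 log2 and 80.8% of changes of 2 log2 were recovered. More genes than that passed in the measured data, so the recovery there may differ.

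**Figure D3:**
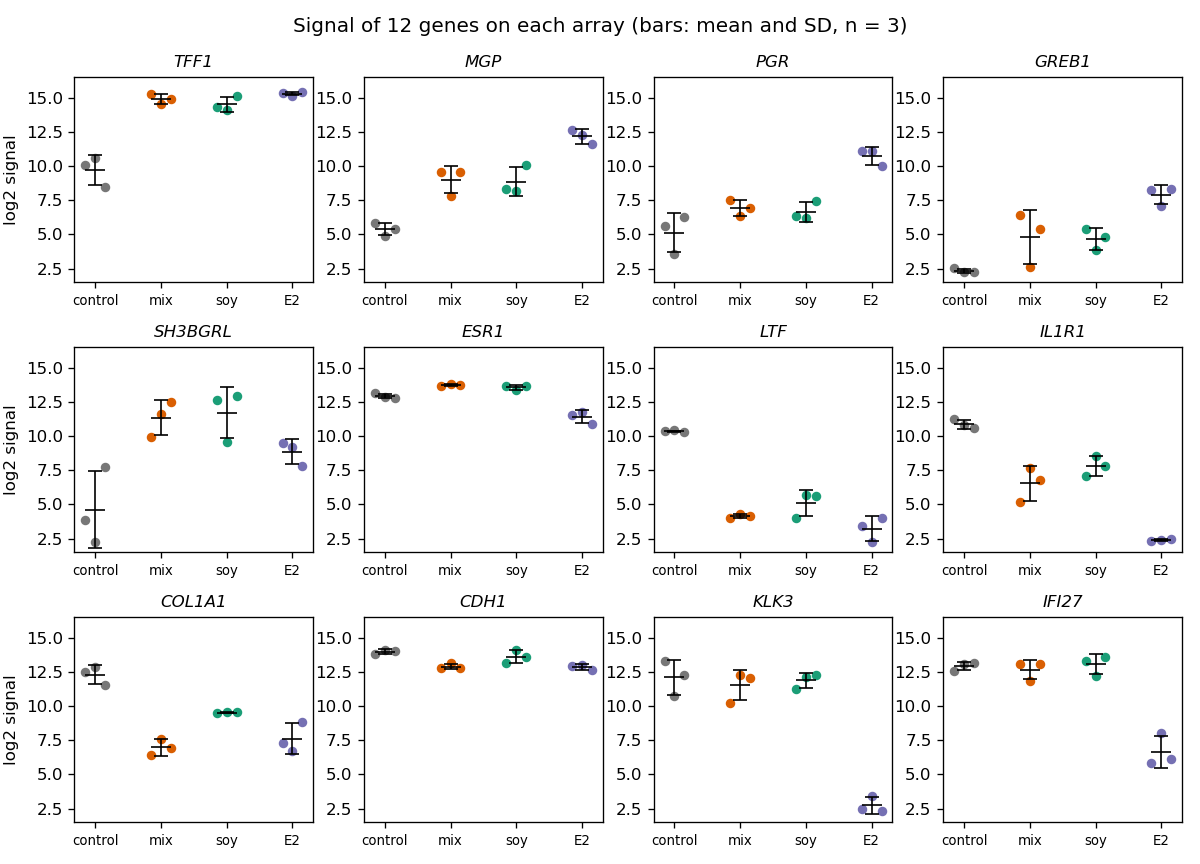
Log2 signal of 12 genes (1 panel each) on every array by group; points are arrays, and black bars give the mean and SD of 3. TFF1 is above control on all arrays of the 3 treated groups, while KLK3 and IFI27 are low on the estradiol arrays.

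Estradiol against control compares tumours of mice with an estradiol pellet and with a sham pellet. PGR, the classic estrogen-induced receptor gene, rose from 5.14 ± 1.40 to 10.74 ± 0.64 log2 (adjusted p = 0.00196). MGP rose by 6.78, TFF1 by 5.58, GREB1 by 5.58 and the transcription factor gene EGR3 by 5.24, with adjusted p from 0.000565 to 0.0048. SPIN4, DLC1 and the long non-coding RNA RMST rose by 5.39, 5.30 and 4.97. The kallikrein genes KLK3, KLK2 and KLK11 fell, with measured differences of -9.37, -8.42 and -6.53. KLK3 went from 12.10 ± 1.28 in control to 2.74 ± 0.61 (adjusted p = 0.000473). GREB1 was at the floor on 2 of the 3 control arrays. Means of KLK3, KLK2, IL1R1 and CDC20B in estradiol and of GREB1 and RMST in control lay under 2.81, the highest array median, beside the floor of 2.25, so these differences can only be lower bounds on the change. IL1R1 fell by 8.46, CDC20B by 7.51 (2 of 3 estradiol arrays at the floor), LTF by 7.12 and NIBAN1 by 5.75. The interferon-induced gene IFI27 fell from 12.95 ± 0.31 to 6.66 ± 1.17.

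Interferon-stimulated genes fell as a group in estradiol tumours: 29 of 35 members fell and 0 rose, 32 when adjusted over the list alone, and the median was -2.82. IFI44 fell by 5.63 (adjusted p = 2e-06), ISG15 by 3.96, PARP9 by 3.47 and HERC6 by 3.26. The camera adjusted p was 2.97e-26, and adjusted p = 0.0623 with an estimated correlation. Estrogen-induced genes rose in 18 of 41 cases with 0 fallen, 23 adjusted over the list alone, with CA12 up by 4.50 and TPD52L1 by 2.63 (camera adjusted p = 1.16e-09; adjusted p = 0.0523 with an estimated correlation). MYC rose by 3.94 (adjusted p = 0.008). Of 15 estrogen-repressed genes, 8 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.000157; adjusted p = 0.0623 with an estimated correlation). BLNK fell by 3.76 and EFNA1 by 1.75, while SYTL5 rose by 3.30. ESR1 fell by 1.53 (adjusted p = 0.00258), and so did GATA3 by 1.55 and the coactivator gene NCOA1 by 2.58, in a list of receptors and cofactors where 7 of 12 fell and 1 rose, 7 and 2 adjusted over the list alone (camera adjusted p = 0.00904; adjusted p = 0.171 with an estimated correlation).

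Many cell-cycle genes rose with estradiol. Of 36 mitotic genes 21 rose and 0 fell (29 adjusted over the list alone), with AURKA up by 1.46, MAD2L1 by 1.62 and MYBL2 by 1.55 (camera adjusted p = 7.38e-16; adjusted p = 0.128 with an estimated correlation). Of 36 genes of the G1/S phase and replication 18 rose and 1 fell (24 and 1 adjusted over the list alone), among them CDK4 by 1.16 and RFC2 by 1.01 (camera adjusted p = 1.2e-10; adjusted p = 0.171 with an estimated correlation). BLM, PALB2 and FANCI rose by 1.82, 1.01 and 1.03 among 19 DNA repair genes, of which 12 rose, 15 adjusted over the list alone (camera adjusted p = 2.29e-07; adjusted p = 0.0523 with an estimated correlation). ATM rose by 1.26 (adjusted p = 0.0237), while MKI67 differed by 0.40 (adjusted p = 0.474) and CCND1 by -0.26 (adjusted p = 0.717). LOX, LDHA and HK2 rose by 3.17, 2.06 and 2.34 among 26 hypoxia-induced genes, of which 7 rose and 1 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00171; adjusted p = 0.409 with an estimated correlation).

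Some epithelial and matrix genes fell with estradiol. CDH1 fell by 1.14 (adjusted p = 0.0122), OCLN by 1.95 and EPCAM by 0.83, and 9 of 21 epithelial genes fell while 12 did not pass, 12 fallen adjusted over the list alone (camera adjusted p = 6.5e-06; adjusted p = 0.171 with an estimated correlation). COL1A1, COL1A2 and POSTN fell by 4.68, 4.23 and 3.15, and 10 of 28 fibroblast and matrix genes fell while 18 did not pass, 13 fallen adjusted over the list alone (camera adjusted p = 5.82e-05; adjusted p = 0.171 with an estimated correlation). The leukocyte markers S100A9, CORO1A and CD74 fell by 3.11 (a lower bound, beside the floor in estradiol), 1.62 and 2.86 among 20, 3 also adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.135 with an estimated correlation). JUNB, JUN and DUSP6 fell by 0.74, 1.42 and 2.66 among 22 immediate early genes, of which 5 fell and 1 rose, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0118; adjusted p = 0.171 with an estimated correlation). RPL19 rose by 0.67, and 8 of 33 ribosomal protein genes rose, 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.5e-06; adjusted p = 0.128 with an estimated correlation). NDUFA9 rose by 0.76, and 4 of 29 genes of oxidative phosphorylation rose, 6 adjusted over the list alone (camera adjusted p = 0.000464; adjusted p = 0.236 with an estimated correlation). TXN, TIPARP and CYP1B1 rose by 0.81, 1.35 and 1.30 among 20 targets of the aryl hydrocarbon receptor and NRF2, 3 also adjusted over the list alone (camera adjusted p = 0.0395; adjusted p = 0.253 with an estimated correlation). The muscle gene MB fell by 1.59, 1 of 14 and 1 adjusted over the list alone (camera adjusted p = 0.00189; adjusted p = 0.297 with an estimated correlation). Of 16 endothelial markers 0 passed in this comparison, also adjusted over the list alone, and 2 of the 16 had a mean at or above the median of all gene values.

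Against control, 1458 genes were higher and 1517 lower in estradiol tumours (limma, Benjamini-Hochberg). Of all genes, 38.1% had no overlap between the arrays of the groups, where chance gives 10%. With each array centred on its median, 61.0% of the calls were higher in place of 49.0%, and the median difference of expressed genes was 0.14 in place of 0.00. The count was 1804 without estradiol array 1, 1863 without estradiol array 2, and 1626 with the signal of the hybridization spikes as a covariate, which was 10.60 ± 0.08 log2 on the estradiol and 11.26 ± 0.31 on the control arrays (exact permutation p = 0.1, the smallest possible).

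**Figure D4:**
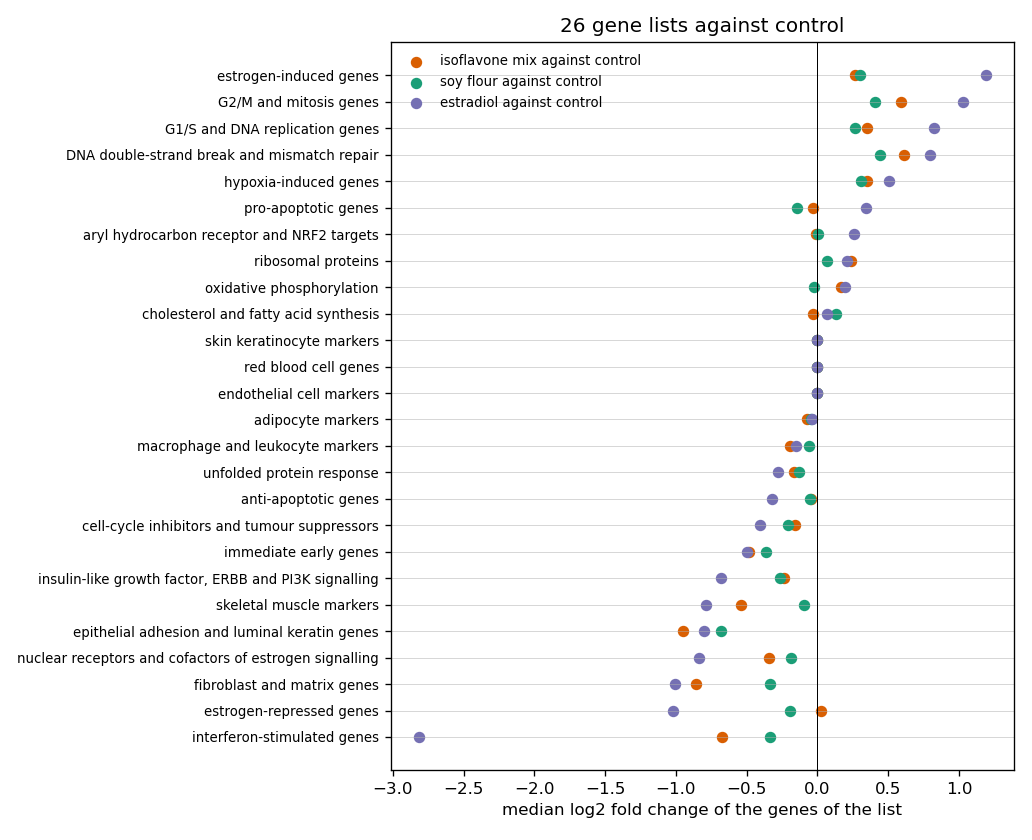
Median log2 fold change against control of the genes of each of 26 lists; orange points are the isoflavone mix, green points soy flour and purple points estradiol. Interferon-stimulated genes lie at -2.82 with estradiol and -0.68 and -0.33 with the mix and soy flour.

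The direct comparison of the diets asks whether soy flour and purified isoflavones act differently at equal genistein. No gene passed the test: limma with Benjamini-Hochberg adjustment called 0 of 19775, with a smallest adjusted p of 0.0638, while 2056 had an unadjusted p under 0.05 where 988.75 are expected by chance. ARHGEF11, an exchange factor for Rho proteins, was 0.87 higher with soy flour (6.34 ± 0.05 against 5.47 ± 0.14, adjusted p = 0.0702). The kinase gene GRK2 was 0.73 higher, the WNT receptor gene FZD4 0.74, BICRA 0.78 and BMS1P1 1.34, each with adjusted p = 0.114. BCL7C was lower, with a difference of -0.53 (8.40 ± 0.07 against 8.93 ± 0.07, adjusted p = 0.0638). SOCS6, a suppressor of cytokine signalling, differed by -0.55 (adjusted p = 0.0638), and NDUFA13, PEX3 and GNGT1 by -0.85, -0.72 and -1.26, each with adjusted p = 0.0702. TFF1 differed by -0.37 (adjusted p = 0.957), PGR by -0.30, GREB1 by -0.12, CCND1 by -0.10 and MYC by 0.26 (each with adjusted p = 1). CDH1 was 0.73 higher with soy flour (adjusted p = 0.309), MKI67 0.63 higher (adjusted p = 0.557), ATM differed by -0.36 (adjusted p = 0.735) and ESR1 by -0.17 (adjusted p = 0.908).

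Interferon-stimulated genes lay higher with soy flour than with the mix as a list, with a median of 0.26, although 0 of 35 passed alone and 3 adjusted over the list alone (camera adjusted p = 3.19e-05; adjusted p = 0.62 with an estimated correlation). IFI44 was 0.90 higher (adjusted p = 0.142) and HLA-B 1.15 higher (adjusted p = 0.197). Fibroblast and matrix genes had a median of 0.07 and a mean of 0.39, with COL1A1 2.55 higher (adjusted p = 0.189) and 0 past the test, also adjusted over the list alone (camera adjusted p = 0.000721; adjusted p = 0.62 with an estimated correlation). Immediate early genes and genes of the unfolded protein response had medians of 0.13 and 0.16 with camera adjusted p of 0.00339 and 0.00737, and 0 passed adjusted over the list alone (adjusted p = 0.62 with an estimated correlation for each). HSPA5 was 0.56 higher (adjusted p = 0.304). Skeletal muscle markers had a median of 0.25, with 0 of 14 past the test, also adjusted over the list alone (camera adjusted p = 0.0396; adjusted p = 0.649 with an estimated correlation). Of 41 estrogen-induced genes 0 passed, also adjusted over the list alone, with a median of -0.05, a mean of -0.07 and a camera test on the higher side (adjusted p = 0.85). Ribosomal protein genes had a median of -0.09, with 0 past the test and 1 lower adjusted over the list alone (camera adjusted p = 0.0193; adjusted p = 0.62 with an estimated correlation).

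The 95% interval of the difference between the diets reached a median of 0.53 log2 to each side over the 9944 genes at or above the median level, and for 66.9% of them it lay within 1 log2 of 0. Of all genes, 11.2% had no overlap between the 3 soy flour and the 3 mix arrays, where chance gives 10%. Without mix array 2 the count was 86, without mix array 3 it was 16, and without soy flour arrays 1 and 2 it was 30 and 10. With each array centred on its median it was 117, 3 higher and 114 lower with soy flour. That scaling moved the median difference of expressed genes from -0.07 to -0.18, so these calls may reflect the scaling.

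The genes that estradiol moved were followed as sets in the diets. The 1458 genes higher in estradiol tumours had a median of 0.52 with the mix and 0.26 with soy flour, against 1.03 with estradiol. The 1517 genes lower in estradiol tumours had medians of -0.76, -0.63 and -1.23. The control arrays that chose the genes also serve the diets, and simulated unchanged diets gave medians of 0.0393 and -0.0517 for the mix and 0.0386 and -0.0501 for soy flour with the measured estradiol effect, or 0.0933 and -0.0900, and 0.0929 and -0.0911, without it. Genes higher in estradiol had the same sign in 87.7% of cases with the mix and 76.3% with soy flour, and genes lower in 90.3% and 91.8%. The simulated shares were 60.7%, 60.7%, 60.4% and 60.2% with the estradiol effect, and 85.6%, 85.6%, 85.2% and 85.4% without it, above the value of soy flour for the genes higher in estradiol. The diet arrays entered the choice of these genes only through the shared spread, the joint normalization and the choice of probe sets. In soy flour against the mix, the first set had a median of -0.24 (camera adjusted p = 6.89e-13, and adjusted p = 0.0411 with an estimated correlation). The second had a median of 0.11 (camera adjusted p = 7.34e-08, and adjusted p = 0.0411 with an estimated correlation). Expressed genes, those above the median level, had a median of -0.07 in this comparison. A part of the -0.24 may thus be a shift shared by expressed genes, while the 0.11 of the second set goes the other way. Limma's fry, which asks whether a set moves on balance, gave adjusted p = 0.0177 and 0.0847. With genes chosen from the 6 estradiol and control arrays alone, a test added after the results were seen, the medians were -0.25 and 0.17 (adjusted p = 0.0549 for each with an estimated correlation). With the actin difference as a covariate the medians were -0.19 and 0.10, and the tests with an estimated correlation gave adjusted p = 0.167 and 0.142.

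Among the genes past the test in both the mix and estradiol against control, 459 were higher in both and 639 lower in both, where independent lists would share 61.3 and 75.6, a value that leaves out the shared control arrays. For soy flour and estradiol the numbers were 101 and 293, against 11.4 and 27.3, and for the mix and soy flour they were 118 and 301, against 6.47 and 17.8. Across genes, which are not independent replicates, the changes with the mix and with estradiol had r = 0.686, where simulated unchanged groups against the same control arrays gave 0.501, and a covariance of 0.312 against 0.0339. The values were r = 0.605 and a covariance of 0.231 for soy flour and estradiol, against 0.50 and 0.0337. For the diets they were 0.829 and 0.250, against 0.50 and 0.0338. The simulated values already hold the spread of the shared control arrays, and the 3 covariances lay 0.278, 0.197 and 0.216 above them. This argues against that spread as the main source of the covariances. With 3 control arrays, no split leaves 2 in each part, so a smaller part of the excess may still come from the shared controls. Both diets also had a higher mean actin 3' minus 5' difference than control, and its part in their correlation was not tested.

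**Figure D5:**
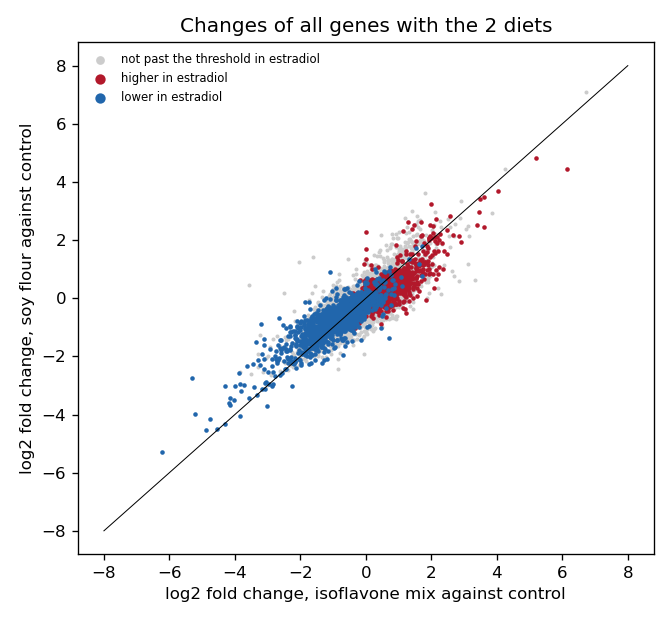
Log2 fold change of each gene with soy flour (vertical) against that with the isoflavone mix (horizontal), both against control; red and blue points are genes higher and lower in estradiol tumours, and the line marks equal changes. Both axes and the colours share the control arrays; genes higher in estradiol have a median of 0.52 with the mix and 0.26 with soy flour, where simulated unchanged diets give 0.0393 and 0.0386.

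Set against estradiol tumours, the diet tumours had more KLK2 and KLK3. KLK2 was 9.14 higher with the mix (11.61 ± 1.25 against 2.47 ± 0.16, adjusted p = 0.00184) and 9.36 higher with soy flour (adjusted p = 0.00144), and KLK3 8.80 and 9.14 higher. IFI27 was 6.01 and 6.39 higher (adjusted p = 0.00222 and 0.00155). HEY1, a transcription factor gene of the Notch pathway, was 5.72 higher with the mix, and CDC20B 6.37 higher with soy flour. KLK2, KLK3 and CDC20B in estradiol and RMST with the mix lay beside the floor, so their differences are lower bounds. RMST, DKK1 and CA12 were lower with the mix than with estradiol, with differences of -5.03, -4.32 and -4.21. The chemokine gene CXCL12, TMPRSS3 and DLC1 were lower with soy flour, by -5.44, -5.03 and -4.25 on the log2 scale. DOK7 was lower with both, with differences of -4.47 and -4.93. ESR1 was 2.33 and 2.16 higher, and PGR differed by -3.79 and -4.08 (adjusted p = 0.0228 and 0.0144).

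TFF1 differed from its estradiol level by -0.40 with the mix (adjusted p = 0.858) and -0.77 with soy flour (adjusted p = 0.495). MYC was lower with the mix by -2.98 log2 (adjusted p = 0.05 after rounding, just past the test) and by -2.72 with soy flour (adjusted p = 0.0571). GREB1 differed by -3.09 and -3.22 (adjusted p = 0.092 and 0.07). CDH1 differed by 0.03 and 0.76, ATM by 0.46 and 0.09, MKI67 by -0.50 and 0.14, and CCND1 by -0.01 and -0.12, none past the test. Interferon-stimulated genes rose against estradiol in 22 of 35 cases with the mix and 24 with soy flour, 24 and 27 adjusted over the list alone (camera adjusted p = 2.8e-25 and 2e-31; adjusted p = 0.0866 and adjusted p = 0.068 with an estimated correlation). Of 41 estrogen-induced genes, 7 were lower with the mix and 12 with soy flour, 20 and 25 adjusted over the list alone with 1 higher with soy flour (camera adjusted p = 1.78e-09 and 2.55e-07; adjusted p = 0.0866 and adjusted p = 0.068 with an estimated correlation).

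The mix differed from estradiol in 490 higher and 529 lower genes, and soy flour in 429 higher and 932 lower genes (limma, Benjamini-Hochberg). With the hybridization spike covariate these totals of 1019 and 1361 became 54 and 89, and with the actin covariate 108 and 907. With each array centred on its median 19.1% of the soy flour calls were higher in place of 31.5%. The first was 463, 570 and 648 without estradiol arrays 1, 2 and 3 and 528 without mix array 2. The second was 578, 769 and 844 without those estradiol arrays, and 819 and 723 without soy flour arrays 1 and 3.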

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

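The tests of the spread of the soy flour arrays, of the estradiol-moved genes, of estradiol genes chosen from 6 arrays, of host cell genes and of the unnamed probe sets on the values as deposited were chosen after the results were seen. The actin, spike and Alu covariates were chosen after these measures were seen to differ between groups, and the jackknife error was set as the spread of the slopes after the slopes were known. Groups of 3 arrays are too small to test a single array for standing apart.

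Measures outside the gene tests drew attention because they lay above their control level. The actin 3' minus 5' difference was 1.84 log2 higher with the isoflavone mix than in control. Probe sets with no gene name were higher than in control in 546 cases with soy flour, in 74 with the isoflavone mix and in 108 with estradiol, of 11721. This order did not hold with the actin covariate, which gave 19, 0 and 53, and the spike covariate gave 435, 56 and 251. Soy flour against the mix called 7 higher and 2 lower.

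More genes passed with the isoflavone mix than with soy flour against control, 1817 against 510. The soy flour arrays did not have a larger spread, with a variance 0.940 times that of the mix. The fit shares 1 estimate of the spread per gene, so a larger spread in 1 diet would enter both counts. With the actin covariate the order turned, to 5 for the mix and 41 for soy flour: changes of the called genes had a slope of 0.896 (jackknife standard error 0.133, 0.801 to 0.967 without 1 array; soy flour 0.959), with a median of 1.05 before and 0.872 after, but calls ended as their median standard error grew from 0.203 to 0.342. A slope of at least 0.8 was set beforehand as the bound against RNA integrity, and 0.896 lies above it by less than its jackknife error, so RNA integrity as a part of the cause and the diet cannot be told apart. A weaker estrogen-type response with soy flour stays open too. Genes higher in estradiol tumours had a median of -0.24 in soy flour against the mix (adjusted p = 0.0411 with an estimated correlation). The same test gave adjusted p = 0.0549 with genes chosen from 6 arrays alone and 0.167 with the actin covariate. Expressed genes had a median of -0.07 in that comparison, so a part of the -0.24 may be a general shift. The fixed estrogen-induced list had a median of -0.05 there without the covariate, with camera adjusted p = 0.85.

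Interferon-stimulated genes were low in estradiol tumours. The quantile normalization added here is argued against, since the median against control was -2.71 on the values as deposited. The submitters' own normalization is not given and was not tested. RNA integrity as read by actin is argued against likewise, since the median was -2.82 with the actin covariate. That actin difference was only 0.359 above control in estradiol (exact permutation p = 0.2), so the covariate had little to remove. The hybridization spikes also differed, at 10.60 ± 0.08 log2 on the estradiol and 11.26 ± 0.31 on the control arrays. The list was not tested with them as a covariate. Fewer host cells stay a candidate explanation for a part of the fall against control. COL3A1 was at 14.5 in control, 12.6 in estradiol, 13.1 with the mix and 14.1 with soy flour. A set of 15 host genes at or above the median level held 12 fibroblast and matrix genes and 3 macrophage and leukocyte genes. It was 1.62 higher in control than in estradiol (upper quartile 2.61), where the interferon list was 2.82 higher. In mix against estradiol the 15 host genes had a median of 0.0728 and an upper quartile of 0.53, where the interferon list had 2.02. This argues against fibroblasts as the cause there, as far as human probe sets read mouse RNA, which the labels do not state. With 3 leukocyte genes in the set, a loss of leukocytes cannot be judged. In soy flour against estradiol, with 0.965 and 1.62 against 2.60, host cells cannot be told apart from the hormone. Against control, the fibroblast and matrix list had a mean of -1.17 with the mix and -1.18 with estradiol. The interferon medians were -0.68 and -2.82. Of the 28 fibroblast and matrix genes 12 lay at or above the median level, so the floor can hide a part of their falls. The 3 most abundant were lower with estradiol than with the mix: COL3A1, VIM (8.74 against 9.22) and FN1 (8.08 against 8.59). The host changes therefore cannot be called equal. The 15 host genes still differed less than the interferon list (0.0728 against 2.02). This argues against fibroblasts as the whole cause with estradiol, as far as human probe sets read mouse RNA. A loss of leukocytes stays open. An effect of estradiol on interferon signalling of the tumour cells stays open as a hypothesis.

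Of 11721 probe sets with no gene name, 546 were called higher and 56 lower with soy flour. The median change was 0 over all of them and 2.30 over those called higher. The quantile normalization added here is argued against, since 599 were higher on the values as deposited. The submitters' own processing is not given and was not tested. With the actin covariate their changes had a slope of 0.878 (jackknife standard error 0.193, 0.761 to 1.04 without 1 array) and 19 stayed past the test, while with the Alu control probe set as covariate the slope was 0.813 (error 0.121, 0.775 to 0.930) and 371 passed, so neither RNA integrity nor unspliced or genomic sequence can be told apart from the diet. The count was 114, 125 and 215 without control arrays 1, 2 and 3, 216, 363 and 207 without soy flour arrays 1, 2 and 3, 255, 346 and 317 without estradiol arrays 1, 2 and 3, and 1007 without mix array 3. No biological explanation was tested for these probe sets.

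Other groupings of the same arrays were tried for each count. For any difference among the 4 groups, 1 of 100 groupings of the 12 arrays, the real one, gave as many as 2859 genes. The highest other gave 429, so chance in the grouping of these arrays is argued against. Regrouping cannot tell a treatment from other differences between the groups, since the labels do not say that each array comes from a separate mouse. Comparisons of 3 arrays with 3 make 10 splits, too few for a share under 0.05. In each of isoflavone mix, soy flour and estradiol against control and of both diets against estradiol, 1 of 10 splits gave as many genes as the real one, itself. The real counts and highest others were 1817 and 0, 510 and 4, 2975 and 4, 1019 and 0, and 1361 and 0. For soy flour against isoflavone mix the real count was 0, so all 10 splits gave as many, and the highest other was 18.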

How the results depend on the processing

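Of the alternatives below, the actin and spike covariates, and for the sets moved by estradiol the values as deposited and the choice from 6 arrays, were chosen after seeing the data. The others were set before the data were examined. Array signal over background limits low genes, and 15069 to 16890 probe sets per array at the floor carry no measured order. A pseudocount was not run, since the table is already log2. Of 186 named results past the test, 170 kept their call on the values as deposited, 181 on centred arrays, 182 without the lowest 40% of genes, 163 with the mean of all probe sets (1 changed direction), 185 with trend and robust, 181 with array weights, 151 with a replicate block, 89 with the actin covariate, 128 with the spike covariate, 88 with only the 6 arrays compared, and 136 to 166 without 1 array. Of 45 list calls, 0 kept theirs with an estimated correlation, 24 with fry, 43 as deposited, 39 without low genes, 38 with the mean of probe sets, 44 with the block, 40 with the actin covariate and 39 to 45 without 1 array. The scaling changed the median difference of expressed genes most for soy flour against estradiol, which was -0.09 in the reported fit, -0.19 as deposited and -0.26 with centred arrays. Fits with 6 arrays or 1 array fewer have fewer degrees of freedom, and tests without low genes adjust over fewer genes. Fits of 6 arrays moved the counts unequally. Estradiol against control went from 2975 to 2283, the mix from 1817 to 329 and soy flour from 510 to 47. The mean variance within groups, which the reported fit pools, also differed. It was 0.119 in control, 0.108 with the mix, 0.101 with soy flour and 0.0760 in estradiol. The cause of the moves was not tested in any setting.

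Isoflavone mix against control called 1817 genes, 5 with the actin covariate, 2862 at adjusted p under 0.1, 329 with 6 arrays and 749 to 1871 without 1 array. Soy flour against control called 510 genes, 1135 without low genes, 785 with the mean of probe sets, 195 with the block, 41 with the actin and 265 with the spike covariate, 823 with every probe set, 1055 at 0.1, 47 with 6 arrays and 109 to 650 without 1 array. Estradiol against control called 2975, 1626 with the spike covariate and 1804 to 3105 without 1 array. Soy flour against the mix called 0, 2 as deposited, and 117 centred (3 higher and 114 lower). The same comparison called 3 with the mean of probe sets, 30 with array weights, 1 with the actin covariate and 7 with every probe set. It called 13 at 0.1, 1 with 6 arrays and 0 to 86 without 1 array. The mix against estradiol called 1019, 1659 without low genes, 2018 with weights, 647 with the block, 108 with the actin and 54 with the spike covariate, 1770 at 0.1, 136 with 6 arrays and 463 to 1260 without 1 array. Soy flour against estradiol called 1361, 2131 without low genes, 3429 with weights, 829 with the block, 907 with the actin and 89 with the spike covariate, 2219 at 0.1, 749 with 6 arrays and 578 to 1613 without 1 array. The F test called 2859, 4484 without low genes, 5008 with weights, 4470 at 0.1, 1793 with the block, 1412 with the actin and 1647 with the spike covariate, and 1420 to 3142 without 1 array. Replicate numbers do not pair samples: over 18 pairs of arrays with the same number, correlations were -0.17 to 0.14, 1 over 0.1, and 0 arrays correlated best with their own number.

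In soy flour against mix, the sets moved by estradiol had medians of -0.34 to -0.17 and 0.06 to 0.19 without 1 array, and -0.19 and 0.10 with the actin covariate, where the estimated correlation gave adjusted p = 0.167 and 0.142. Chosen from the 6 estradiol and control arrays alone, the sets had 1199 and 1084 genes and medians of -0.25 and 0.17, with adjusted p = 0.0549 for each with an estimated correlation. Correlations of changes without 1 array were 0.644 to 0.712 for mix and estradiol, 0.561 to 0.634 for soy flour and estradiol and 0.781 to 0.847 for the diets. The list of G1/S and replication genes turned direction in mix against control with the actin covariate (adjusted p = 0.187). With the mean of all probe sets, signs turned for ESR1 (-0.30) and LOX (-0.16) in mix against control, for SOCS6 (0.0913), PEX3 (0.00208) and ESR1 (0.63) in soy flour against mix, for CCND1 (0.15), CDH1 (-1.35) and ATM (-0.0455) in mix against estradiol, and for CCND1 (0.10), MKI67 (-0.15) and ATM (-0.20) in soy flour against estradiol. LOX alone of these had passed the test. With the actin covariate, GREB1 (0.29), CCND1 (0.0446) and MYC (-0.64) turned in soy flour against mix, TFF1 (0.0591) in mix against estradiol and ATM (-0.0534) in soy flour against estradiol. With array weights, CCND1 (0.30) and CDH1 (-0.0433) turned in mix against estradiol, and CCND1 (0.22) and ATM (-0.13) in soy flour against estradiol. As deposited, CDH1 (-0.0576) turned in mix against estradiol and ATM (-0.0233) in soy flour against estradiol. With centred arrays these were CDH1 (-0.0803), and MKI67 (-0.0542) and ATM (-0.0929) in the same comparisons, and with the spike covariate MKI67 (-0.35) turned in soy flour against estradiol. Without 1 array, MKI67 ran from -0.30 to 0.0553 in mix against control, and in soy flour against mix GREB1 from -1.22 to 0.68, CCND1 from -0.21 to 0.0505 and MYC from -0.33 to 0.88. In mix against estradiol CCND1 ran from -0.26 to 0.35 and CDH1 from -0.0893 to 0.12. In soy flour against estradiol CCND1 ran from -0.36 to 0.25, MKI67 from -0.0540 to 0.49 and ATM from -0.0495 to 0.30.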

Other observations

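Some growth factor and lipid genes differed in estradiol tumours, in lists that did not pass. Of 23 genes of insulin-like growth factor, ERBB and PI3K signalling, 9 fell and 1 rose, with ERBB4 down by 3.30, INSR by 2.13 and IGFBP2 by 2.04, and FGFR4 up by 2.43 (camera adjusted p = 0.0522). FGFR4 rose with the mix and with soy flour too, by 2.25 and 2.19. Of 21 genes of cholesterol and fatty acid synthesis 2 rose and 2 fell (camera adjusted p = 0.656): the cholesterol transport gene STARD4 rose by 3.85 and ACLY by 0.73, while the fatty acid gene ACACA fell by 1.66 and its regulator SREBF1 by 1.99. Of 19 pro-apoptotic genes 5 rose and 3 fell (camera adjusted p = 0.07), with BID, CYCS and HRK up by 1.26, 1.40 and 1.21 and BIK down by 2.02. Of 13 anti-apoptotic genes 0 rose and 2 fell, MCL1 by 0.58 and BIRC2 by 0.41 (camera adjusted p = 0.163).

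A hypothesis is that purified isoflavones give a stronger estrogen-type response than soy flour at equal genistein. The test run here was the median of the genes higher in estradiol tumours, in soy flour against the mix: it was -0.24 (adjusted p = 0.0411 with an estimated correlation), -0.25 when 6 arrays alone chose the genes (adjusted p = 0.0549), and -0.19 with the actin covariate, where the test with an estimated correlation gave adjusted p = 0.167. This was written as a test of the hypothesis after the direction had been seen. The fixed list of 41 estrogen-induced genes showed no such difference past the test (median -0.05, camera adjusted p = 0.85). Expressed genes had a median of -0.07 in that comparison, so a part of the -0.24 may be a general shift. More tumours per diet, with RNA integrity matched before labelling and dates balanced over groups, would separate the explanations. Measuring serum genistein and estradiol in the same mice would show whether dose differs.

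A further hypothesis is that estradiol lowers interferon signalling in the tumour cells, while the isoflavones do so less. The tests run here argued against the added quantile normalization (median -2.71 as deposited). They argued against fewer fibroblasts than in the mix tumours as the cause (host median 0.0728), as far as human probe sets read mouse RNA. Of the 15 host genes 12 were fibroblast and matrix genes, so a loss of leukocytes was not decided. Host cells stay open as a part of the fall against control (1.62) and for soy flour (0.965). MCF-7 cells in culture, treated with estradiol or genistein with and without an estrogen receptor blocker, would separate tumour cells from host cells. Reads mapped to human and mouse genomes apart would also show how much of the change in collagen and leukocyte genes comes from human cells.

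The last hypothesis is that the 546 unnamed probe sets higher with soy flour carry unspliced RNA or genomic sequence. Quantitative PCR across introns, with and without reverse transcriptase, would test it. The test run here, a slope of 0.813 with the Alu covariate, did not decide it.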
